A study of Mus musculus with 6 samples.

How the data were processed

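RNA of sorted liver CD8+ T cells was labelled with 1 colour (Cy3) and read on Agilent arrays of 45018 spots, with an array for each of 6 samples, 3 TGC3 and 3 TG, grouped by the genotype in their labels. Nothing beyond the sample codes says that the arrays came from separate mice, so that p-values measure the spread between these samples. Per the file headers, spots were read with Feature Extraction 10.7.3.1, while the submitters' processing notes name 10.7.1.1. Per the file headers, the processed signal is an intensity after background subtraction and detrending within each array, with no normalization between arrays, and the mean and background signals are raw intensity values. The deposited matrix of normalized values is on a log2 scale: its 6 columns had the same median (5.57) and sorted values, as quantile normalization gives, and correlated across probes at 0.999 to 1.00 with the log2 of the processed signal. How it was made beyond this is not stated, and it was used as an alternative. All columns mapped to samples (0 unmapped).

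Of the spots, 43379 were not controls and held 41174 distinct probes, 245 of them with several spots, which were averaged on the log2 scale. Saturated spots numbered 0, and 11 probes were left out for spots the software marked as outliers. The log2 processed signal was scaled by subtracting each array's 75th percentile over these probes. Probes well above background on at least 3 of 6 arrays were kept, whatever the group: 25103 probes, of which 23220 were above background on all 6 arrays, while 13298 of all probes were on none. Probe names were updated from RefSeq records by accession (27668 probes), by a current symbol (5589) or by a synonym of 1 gene (471), and 7446 kept the name in the files, 27343 distinct names in all. Each gene was read by its brightest kept probe, which gave 16389 genes. Probe positions are those of mm9 in the files. The well above background call sets the depth, since the arrays give no counts.

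TGC3 was compared with TG with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3 with data.table (version 1.17.8) and statmod 1.5.0, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9, and probe names were handled with pandas 2.3.3. Of 36 gene lists, 35 had at least 5 tested genes and were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Counts of members past the threshold were also adjusted over the list alone. Medians of lists were set against those of 10000 random lists of the same size matched on 10 classes of mean signal.

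The lists, the limma, camera and fry tests, the thresholds and the rule for named genes were chosen before the data were examined, and the comparison with random lists after the result was seen. The rule takes Cxcr3, Cd8a, Cd8b1, Cd3e, Tgfbr2, Mki67, Ifng, Gzmb and Cd69, the 12 largest fitted increases and 12 largest fitted decreases past the threshold with separate groups and a gene symbol rather than a model or clone name, and up to 4 members of each list with the largest change past the threshold. It gave 141 genes. The text gives all of the first 2 parts, up to 4 members for the 5 lists tied to activation and proliferation and the first 2 for the other lists, a limit set for length after the values were seen. The results of some of these genes are not reported here. Of the 141, 135 passed the threshold and 69 of these passed without any 1 array. A gene above background on no array of a group, or on some only, is given as a bound on its fold.

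The procedure was tested on simulated data made from the within-group spread. It found 33 of 67 genes changed 1.5-fold, 58 of 67 changed 2-fold and 64 of 66 changed 4-fold, and called 15 of 16189 unchanged genes and 0 genes when none was changed. With only the S phase list shifted, 1 list was called, and with none shifted, 0. The simulated genes were drawn independently of one another. In the data the estimated correlation was 0.73 for S phase and 0.78 for G2 and M phase genes. The simulation thus cannot show how often camera calls lists whose genes vary together.

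Alternatives were quantile normalization, centring on the median, the deposited normalized values, normexp background correction with an offset of 50, no filter, a filter on all 6 arrays, the mean or most variable probe of a gene, eBayes with trend and robust settings, array weights, the replicate number as a block, and leaving out each array in turn. After the data were seen, cyclic loess normalization, genes above the median signal only, and normexp with aberrant spot backgrounds (over 10 times the array's median) replaced by that median were added. The design has no untreated or wild-type samples, so no background level from such samples can be given.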

Results

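Gene expression was measured in CD8+ T cells sorted from the livers of female C57BL/6 mice aged 13 to 14 weeks. All mice carried dnTGFβRII, a transgene for a dominant negative TGF-beta receptor II (TG). The TGC3 group also lacked the chemokine receptor CXCR3. Each group had 3 samples. Each sample was read on 1 one-colour array, named here by group and replicate (TGC3 1 to TGC3 3, TG 1 to TG 3). Between 58.9% (TGC3 1) and 63.8% (TGC3 2) of the 41174 probes lay well above background on an array, with 60.9% on TGC3 3 and 61.4%, 60.7% and 59.99% on TG 1 to TG 3. The 75th percentile of the signal was 594, 611 and 623 intensity units on TGC3 1 to TGC3 3 and 561, 573 and 620 on TG 1 to TG 3. Across genes, which are not independent replicates, arrays correlated at 0.993 to 0.994 within TGC3, 0.994 to 0.995 within TG and 0.983 to 0.986 between the groups. The first principal component held 61.3% of the variance and separated the groups. The second held 12.1% and set TGC3 2 (-24.9) apart from TGC3 1 and TGC3 3 (16.7 and 10.6), with the TG arrays between -11.0 and 7.31. The number of arrays limits the precision. All 3 TGC3 arrays lay on 1 slide and all 3 TG arrays on the other, each scanned in its own run, so that slide and genotype cannot be told apart for any difference given here.

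The comparison asked how the loss of CXCR3 changes the transcriptome of these cells, with activation and proliferation named by the study as its subject. Changes are log2 values of TGC3 minus TG ± standard error from limma, with 3 arrays in each group and p adjusted over 16389 genes.

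Cxcr3 itself, the gene deleted in TGC3 and the receptor for CXCL9, CXCL10 and CXCL11, was read by 1 probe (NM_009910, mm9, chromosome X, 98926920 to 98926979, minus strand) with the sequence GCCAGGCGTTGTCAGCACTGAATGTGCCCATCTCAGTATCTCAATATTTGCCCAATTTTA. Its signal was 23.8, 33.0 and 27.0 intensity units on TGC3 1 to TGC3 3 and 68779, 66107 and 73352 on TG 1 to TG 3. After scaling, the log2 values were -4.64, -4.21 and -4.53 in TGC3 and 6.94, 6.85 and 6.89 in TG. The change was -11.35 ± 0.12 (adjusted p = 9.7e-07), a signal 2615-fold higher in TG than in TGC3. The probe was called well above background on all 6 arrays, and the labels do not say which part of the gene was deleted.

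Across all genes tested, 2721 were higher and 1552 lower in TGC3, together 26.1% of the genes, and in all 4273 the 3 TGC3 values did not overlap the 3 TG values. Of these, 512 were at least 2-fold higher and 90 at least 2-fold lower. Thus 85.0% of the larger changes were upwards, against 63.7% of all calls. Groups did not overlap for 7655 genes (46.7%), where chance gives 10%. Genes of low signal carried much of the upward excess, with a median change of 0.33 in the dimmest decile of genes (443 higher, 93 lower) and -0.08 in the brightest (90 higher, 193 lower). Among genes above the median signal alone, 736 were higher and 1379 lower (34.8% higher), 79 and 16 of them by at least 2-fold. With a normexp background correction in which 7 aberrant spot backgrounds of TG 3 were replaced, 2039 were higher and 1873 lower (52.1% higher), 153 and 28 of them by at least 2-fold. Normexp on the unrepaired backgrounds left 0 genes higher and 1 lower in limma, with 507 genes at an unadjusted p under 0.05 against 6564 in the values reported here. The lower count was 738 and 756 without TGC3 1 and TGC3 3, and 572, 610 and 814 without TG 1, TG 2 and TG 3. The higher count was 1756 without TG 2, and the count at least 2-fold lower was 136 without TGC3 2. With the replicate number as a block 1790 were higher and 553 lower, with no filter 579 were lower, with array weights 2420 were lower and 138 at least 2-fold lower, and with a filter on all 6 arrays 46 were at least 2-fold lower.

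**Figure D1:**
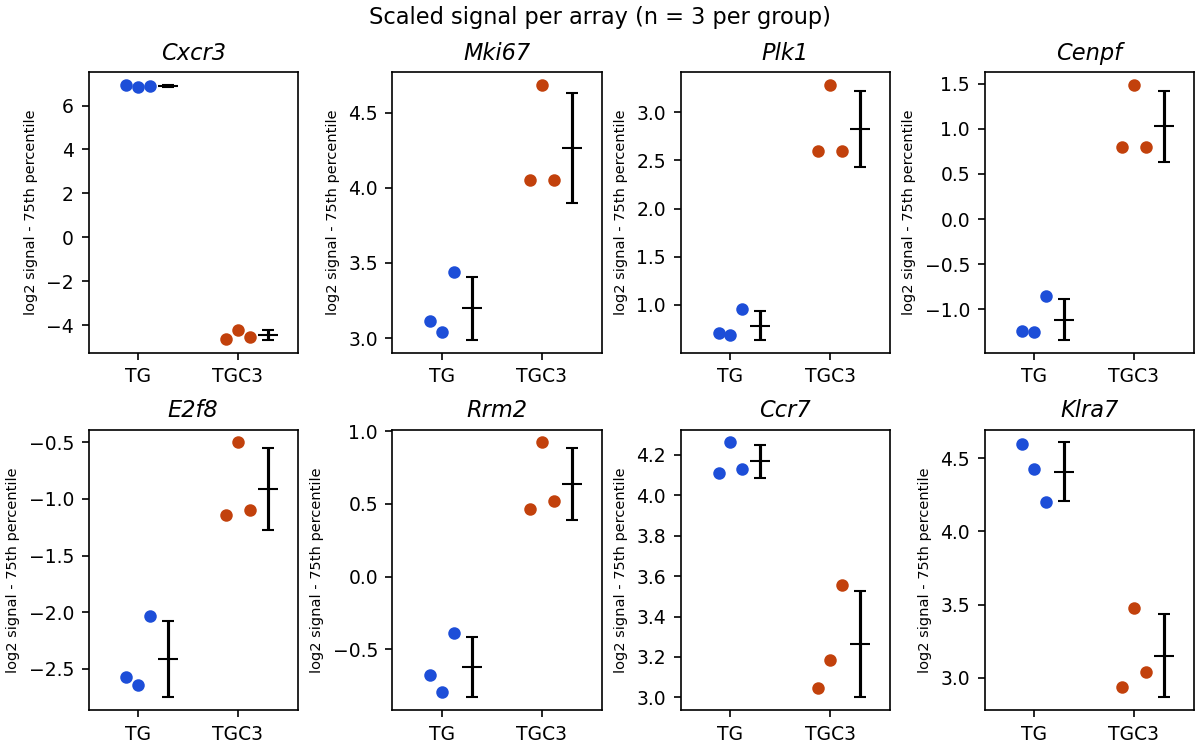
Points are single arrays (3 TGC3, 3 TG), with the mean and SD of each group, for Cxcr3, Mki67, Plk1, Cenpf, E2f8, Rrm2, Ccr7 and Klra7; the vertical axis is the log2 signal minus the array's 75th percentile. Cxcr3 lay between -4.64 and -4.21 in TGC3 and between 6.85 and 6.94 in TG, and the groups did not overlap for any of the 8 genes.

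Genes of the G2 and M phases of the cell cycle rose together in TGC3 cells. Of 62 measured, 55 were higher and 0 lower (57 higher and 0 lower when adjusted over the list alone), and the median change of 1.27 was a 2.42-fold increase. Cenpf, a kinetochore protein (NM_001081363, mm9, chromosome 1, 191465934 to 191465993), rose from -1.11 ± 0.23 in TG to 1.03 ± 0.40 in TGC3 (SD, n = 3), a change of 2.14 ± 0.22 (adjusted p = 0.00287). Gtse1, expressed in G2 and S phase (2.12 ± 0.15, adjusted p = 0.00120), Nusap1, a spindle microtubule protein (2.12 ± 0.24, adjusted p = 0.00371), and Plk1, a mitotic kinase (2.04 ± 0.20, adjusted p = 0.00274), rose by similar amounts. Mki67, which encodes the proliferation marker Ki-67 (NM_001081117, mm9, chromosome 7, 142881591 to 142881650), rose 2.09-fold (1.07 ± 0.20, adjusted p = 0.0149). It was not past the threshold without TG 1 or TG 2 (adjusted p = 0.0511 to 0.0525). The list was called with camera at a preset correlation (adjusted p = 1.0e-19) and with fry (adjusted p = 0.0175), and its median lay above the highest of 10000 random lists matched on signal (0.09). With an estimated correlation the adjusted p was 0.554. Markers of some other cell types had positive medians on the same arrays, 2.98 for neutrophil, 0.69 for B cell, 0.64 for hepatocyte and 0.48 for dendritic cell markers, which turned to -0.10, -0.35, -0.60 and -0.15 with the unrepaired normexp correction but were 0.77, 0.25, 0.14 and 0.26 with the repaired one. With values not well above background raised to the lowest value above it, the neutrophil and hepatocyte medians were 1.83 and 0.32 and the B cell and dendritic cell ones unchanged. These medians rest on 5 of 17 neutrophil, 10 of 18 B cell, 6 of 28 hepatocyte and 14 of 20 dendritic cell markers. Among genes above the median signal the B cell and dendritic cell medians were -0.54 (2 genes) and -0.10 (6 genes), with 0 neutrophil markers and 1 hepatocyte marker left. TGC3 2 read highest of the 6 arrays for cell cycle genes such as Cenpf (1.48, against 0.80 and 0.79 on TGC3 1 and TGC3 3) and Plk1 (3.28 against 2.60 and 2.60), and also for the macrophage marker Lyz2 (1.16 against -1.62 and -0.82). Without TGC3 2 the neutrophil, hepatocyte and dendritic cell medians fell to 2.19, 0.57 and 0.36. The macrophage and B cell medians hardly moved (0.34 and 0.695 against 0.35 and 0.69), and the cholangiocyte median rose from 0.46 to 0.61. Without TGC3 2 the median of the G2 and M phase list was 1.098, with 53 genes higher and 0 lower (camera adjusted p = 1.9e-22). The number higher was 49 without TGC3 1, 50 without TGC3 3, 45 without TG 1, 43 without TG 2 and 54 without TG 3.

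S phase genes also rose. Of 52 measured, 28 were higher and 0 lower (36 higher and 0 lower when adjusted over the list alone), with a median change of 0.49, or 1.40-fold. Among the largest were E2f8, a repressor of the E2F family (2.83-fold higher, adjusted p = 0.00850), Rrm2, a subunit of ribonucleotide reductase (1.26 ± 0.16, adjusted p = 0.00492), and the DNA repair gene Rad51ap1 (1.22 ± 0.24, adjusted p = 0.0161). Rad51ap1 did not pass without TG 1 (adjusted p = 0.0535), and the number higher was 9 without TG 1 and 11 without TG 2. Camera called the list (adjusted p = 3.2e-08), but fry did not (adjusted p = 0.0646), and the adjusted p was 0.686 with an estimated correlation. The marker medians given with the G2 and M phase genes stand beside this list too.

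**Figure D2:**
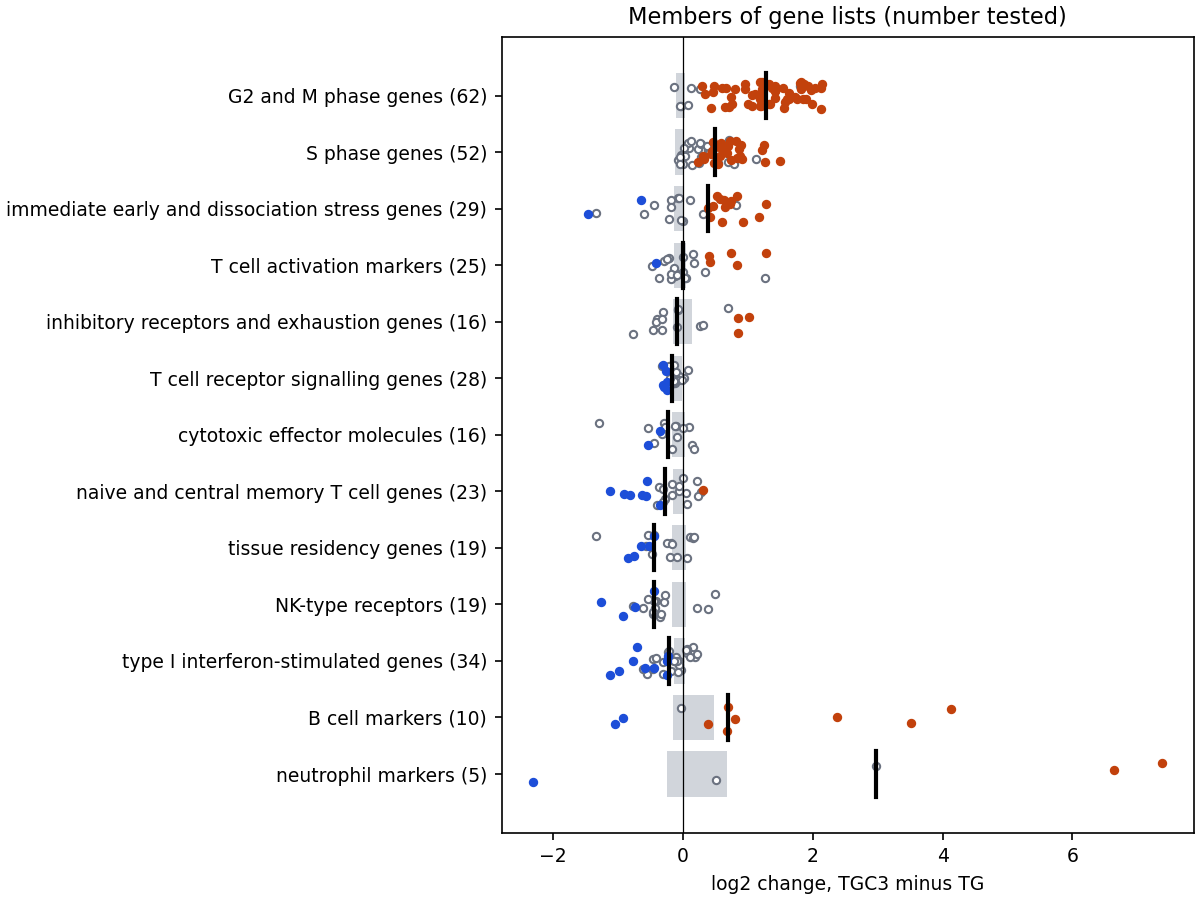
Each point is a gene of 1 of 13 lists, and the horizontal axis is its log2 change (TGC3 minus TG, 3 arrays each), with filled red points past the threshold and higher, filled blue points past it and lower, open points not past it, black bars for list medians and grey boxes for the central 95% of medians of random lists matched on signal. The median was 1.27 for G2 and M phase genes and 0.49 for S phase genes, each beyond its grey box.

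Of 25 T cell activation markers measured, 5 were higher and 1 lower (7 and 2 when adjusted over the list alone). Egr1 (1.27 ± 0.22, adjusted p = 0.0118), Nr4a1 (0.83 ± 0.15, adjusted p = 0.0130) and Nr4a2 (0.74 ± 0.20, adjusted p = 0.0386), transcription factors induced by T cell receptor signals among others, rose. Egr1 and Nr4a1 also belong to the immediate early and dissociation stress genes, of which 14 of 29 were higher and 2 lower (median 0.39, above all 10000 random lists matched on signal). Cd5, a negative regulator of that signal, fell (-0.41 ± 0.11, adjusted p = 0.0349). Cd69, an early activation marker, had a change of -0.48 ± 0.19 that did not pass (adjusted p = 0.112). The list as a whole did not pass (adjusted p = 0.828, and 0.894 with an estimated correlation), with a median of -0.01, a mean of 0.11 and a test that pointed downwards. Nr4a2 did not pass without any 1 of the TGC3 arrays or without TG 2 (adjusted p = 0.0627 to 0.108), nor Cd5 without any 1 array other than TGC3 2 (0.0699 to 0.0989). The number higher was 2 without TGC3 1 or TGC3 3 and 3 without TG 1 or TG 2. The number lower was 2 without TGC3 2 and 0 without TGC3 3 or any 1 TG array.

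Genes of cytotoxicity fell slightly as a list. Of 16 measured, 0 were higher and 2 lower over all genes and when adjusted over the list alone, with a median change of -0.23. Both were lower by less than 2-fold: Fasl, the ligand that triggers apoptosis through Fas (-0.54 ± 0.11, adjusted p = 0.0200), and Ctsw, a cathepsin of cytotoxic lymphocytes (-0.36 ± 0.07, adjusted p = 0.0142). Gzmb, the protease granzyme B, had a change of -0.29 ± 0.21 that did not pass (adjusted p = 0.344). Fasl did not pass without TGC3 2, TGC3 3 or TG 2 (adjusted p = 0.0510 to 0.0636), nor Ctsw without TG 1 or TG 2 (0.0515 to 0.0530). The number lower was 5 without TGC3 2 (1 higher), 1 without TGC3 3 or TG 1 and 0 without TG 2, and the median -0.14 without TGC3 3 or TG 3. On the same arrays the medians of neutrophil, B cell, hepatocyte and dendritic cell markers were 1.83, 0.69, 0.32 and 0.48 at the bounds. They were 0.77, 0.25, 0.14 and 0.26 with the repaired normexp correction. Camera gave the list an adjusted p of 0.0262, against 0.686 with an estimated correlation and 0.0962 with fry. Without TGC3 3 and TG 3 it was 0.0668 and 0.0607, and after quantile normalization 0.0571. Its direction was opposite, without passing, with the unrepaired normexp correction (adjusted p = 0.546), and it stayed lower with the repaired one (0.0252).

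Naive and central memory T cell genes fell as a list. Of 23 measured, 1 was higher and 7 lower (2 and 10 when adjusted over the list alone), with a median change of -0.28. The 3 largest changes were those of Ccr9, a gut homing receptor (-1.13 ± 0.09, adjusted p = 0.00168), Ccr7, the receptor that guides T cells into lymph nodes (-0.91 ± 0.14, adjusted p = 0.00791), and Dapl1 (-0.81 ± 0.16, adjusted p = 0.0150). Without TGC3 3, TG 1 or TG 2, Dapl1 did not pass (adjusted p = 0.0501 to 0.0516), and the number lower was 4. The number higher was 0 without any 1 array other than TGC3 1. Beside this list, too, neutrophil, B cell, hepatocyte and dendritic cell markers had medians of 1.83, 0.69, 0.32 and 0.48 at the bounds. Camera gave the list an adjusted p of 0.0174 and fry 0.0175, against 0.554 with an estimated correlation. It was not called after quantile normalization (adjusted p = 0.0933). With the unrepaired normexp correction its test pointed upwards, without passing (adjusted p = 0.760), while its median stayed below 0 (-0.04). The list was lower with the repaired one (0.0252).

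Receptors shared with NK cells were called lower as a list by camera at the preset correlation, but not at an estimated one. Of 19 measured, 0 were higher, 4 lower (5 when adjusted over the list alone) and 15 past the threshold neither way, with a median change of -0.44. The largest were the Ly49 family gene Klra7 (-1.26 ± 0.17, adjusted p = 0.00563) and the signalling chain Fcer1g (-0.93 ± 0.20, adjusted p = 0.0231). Tissue residency genes were also called lower by camera at the preset correlation, but not at an estimated one or by fry. Of 19 measured, 0 were higher and 5 lower over all genes and over the list alone, with a median of -0.45. Over all genes, 14 passed neither way. The largest past the threshold were those of Rgs1, a regulator of chemokine signalling (-0.85 ± 0.14, adjusted p = 0.00883), and the collagen-binding integrin Itga1 (-0.75 ± 0.19, adjusted p = 0.0342). Only 1 of the 4 Itga1 probes passed (-0.75 to -0.36). Each list had an adjusted p of 0.00869 with camera and of 0.554 with an estimated correlation, and fry gave 0.0196 and 0.0646. Markers of NK, NKT and innate lymphoid cells did not pass as a list on these arrays (13 measured, 2 higher and 3 lower, 2 and 4 over the list alone, median -0.15, or 0.02 without TGC3 1, adjusted p = 0.814). Of these, Il1rl1, the IL-33 receptor, was at least 3.70-fold higher (adjusted p = 0.00436, measured on 1 of 3 TG arrays). Styk1 was 2.41-fold lower (adjusted p = 0.0123, measured on 2 of 3 TGC3 arrays), where the bound equals the fitted fold. Both measured markers of gamma-delta T cells, the scavenger receptor genes 5830411N06Rik (-1.36 ± 0.14, adjusted p = 0.00273) and Cd163l1 (-1.35 ± 0.22, adjusted p = 0.00893), fell, too few for a test of the list. Fcer1g did not pass without TGC3 2, TGC3 3, TG 1 or TG 2 (adjusted p = 0.0534 to 0.0647), nor Itga1 without TGC3 3 or any 1 TG array (0.0620 to 0.0994). The number of NK-type receptors lower was 8 without TGC3 2, 2 without TGC3 3 and 1 without TG 1 or TG 2, and that of residency genes 2 without TGC3 3 or any 1 TG array and 3 after quantile normalization. The NK-type median was -0.28 without TGC3 3 and the residency median -0.29 without TGC3 2. The positive medians of other cell types (at the bounds, neutrophil 1.83, B cell 0.69, hepatocyte 0.32, dendritic cell 0.48) stand beside both lists. Among genes above the median signal neither list passed (adjusted p = 0.155 and 0.176), nor did residency with weighted arrays (0.0566). With the unrepaired normexp correction the adjusted p was 0.429 for NK-type receptors and 0.695 for residency, and with the repaired one 0.0161 for both.

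Genes of T cell receptor signalling were lower by small amounts. Of 28 measured, 0 were higher and 6 lower (3 when adjusted over the list alone), with a median of -0.17 and 26 of 28 changes below 0. Random lists matched on signal were also lower, with a median of -0.08, so that part of this fall is shared by genes of like signal. The list's median lay at percentile 0.58 of these random lists. Cbl, a ubiquitin ligase (-0.32 ± 0.07, adjusted p = 0.0228), was the largest past the threshold. Cd8a and Cd8b1, the chains of CD8, did not pass (-0.20 ± 0.10, adjusted p = 0.200, and -0.08 ± 0.08, adjusted p = 0.463), nor did Cd3e (-0.22 ± 0.07, adjusted p = 0.0517), for which 1 of 2 probes passed. For Cbl, 1 of 2 probes passed. The list had an adjusted p of 4.5e-04 with camera, 0.0175 with fry and 0.554 with an estimated correlation. It turned upwards with the unrepaired normexp correction (adjusted p = 0.0220), but with the repaired one 0 were higher and 8 lower, with a median of -0.18 (adjusted p = 6.5e-04). After quantile normalization and with the deposited normalized values 2 were lower (adjusted p = 0.0222 and 0.0230), as after cyclic loess normalization, where the median was -0.09 (0.0276). Cbl did not pass without TGC3 3, TG 1 or TG 3 (adjusted p = 0.0637 to 0.0785), and the number lower was 0 without TG 1 and 1 without TGC3 1, TGC3 3, TG 2 or TG 3. Markers of neutrophils, B cells, hepatocytes and dendritic cells had medians of 1.83, 0.69, 0.32 and 0.48 at the bounds on these arrays.

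Cytokine receptors and JAK-STAT genes fell as a list, with 4 of 34 higher and 10 lower (4 and 12 over the list alone) and a median of -0.21. The 2 largest changes were nevertheless upwards, in Il1rl1 (at least 3.70-fold) and in Socs2, a feedback inhibitor of cytokine signals (0.83 ± 0.16, adjusted p = 0.0148). For Socs2, 1 of 2 probes passed, and it did not pass without TG 1 (adjusted p = 0.0507). The list's adjusted p was 0.0153 with camera, 0.0569 with fry, 0.563 with an estimated correlation and 0.0712 after quantile normalization. With the unrepaired normexp correction it pointed upwards (adjusted p = 0.124), and with the repaired one downwards (0.0202). The number lower was 4 after quantile or cyclic loess normalization and with the deposited normalized values, 4 without TGC3 1, 2 without TGC3 3 and 1 without any 1 TG array, and the number higher 2 without TG 1. The same markers of other cells (1.83, 0.69, 0.32 and 0.48 at the bounds) stand beside this list. Chemokine receptors did not pass with camera (13 measured, 1 higher and 4 lower, 2 and 5 over the list alone, median -0.19, adjusted p = 0.146, and 0.554 with an estimated correlation) but did with fry (adjusted p = 0.0165). Cxcr5, the receptor for CXCL13, fell most (-1.53 ± 0.14, adjusted p = 0.00226), followed by Ccr9 (-1.13 ± 0.09). It was also the largest change among 12 markers of CD4 and regulatory T cells, of which 1 was higher and 2 lower (1 and 3 over the list alone, median -0.18, adjusted p = 0.294). Without TGC3 2, 3 of these markers were higher and 2 lower, with a median of -0.02. After Cxcr5, the next largest change among them was that of Izumo1r, the folate receptor 4 gene (-0.74 ± 0.18, adjusted p = 0.0278). Izumo1r did not pass without TGC3 1 or any 1 TG array (adjusted p = 0.0599 to 0.0849).

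Effector cytokines and chemokines did not pass as a list (15 measured, 3 higher and 2 lower, 4 and 2 over the list alone, median -0.12, adjusted p = 0.873). The median was 0.02 without TGC3 1 and 0.08 without TGC3 2. Ifng, the gene of interferon-gamma, rose (0.59 ± 0.16, adjusted p = 0.0391), Ccl1 rose (1.22 ± 0.24, adjusted p = 0.0170) and Il4 fell (-1.32 ± 0.13, adjusted p = 0.00241). For Ifng 1 of 2 probes passed, and it did not pass without TGC3 1, TGC3 3, TG 1 or TG 2 (adjusted p = 0.101 to 0.107). Ccl1 did not pass without TGC3 3, TG 1 or TG 2 (0.0543 to 0.0556). Of 16 inhibitory receptors and exhaustion genes, 3 were higher and 0 lower (2 and 0 over the list alone), with a median of -0.09, a mean of 0.05 and a test that pointed downwards (adjusted p = 0.825). These included Rgs16 (1.02 ± 0.17, adjusted p = 0.00966) and Cd200 (0.85 ± 0.18, adjusted p = 0.0200), the latter not past the threshold without TGC3 1, TGC3 2, TG 1 or TG 2 (0.0532 to 0.0653). Among 18 effector and memory transcription factors, 3 were higher and 1 lower (4 and 1 over the list alone, median 0.03, adjusted p = 0.848), led by Rora (0.91 ± 0.08, adjusted p = 0.00198) and Zeb2 (0.80 ± 0.18, adjusted p = 0.0226). Zeb2 passed with 4 of 5 probes and did not pass without TGC3 3, TG 1 or TG 2 (0.0531 to 0.0664).

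Adhesion and migration genes did not pass as a list (25 measured, 2 higher and 2 lower, 1 and 1 over the list alone, median -0.10, adjusted p = 0.346). Itga4, the alpha chain of VLA-4, rose (0.83 ± 0.06, adjusted p = 0.00128) with 5 of 6 probes, and Itga1 fell (-0.75 ± 0.19, not past the threshold without TGC3 3 or any 1 TG array, adjusted p = 0.0620 to 0.0994). TGF-beta pathway genes did not pass either (22 measured, 2 higher and 3 lower, 2 and 2 over the list alone, adjusted p = 0.506), with a median of -0.11 (-0.04 without TGC3 2), a mean of 0.04 and a test that pointed downwards. Ltbp1, a latent TGF-beta binding protein, was at least 2.24-fold higher (adjusted p = 0.00528, measured on 2 of 3 TG arrays), and the receptor gene Acvr1 (0.60 ± 0.14, adjusted p = 0.0297) did not pass without any 1 TGC3 array or without TG 3 (0.0660 to 0.0756). Tgfbr2, which encodes the receptor that the transgene blocks, did not pass (-0.15 ± 0.07, adjusted p = 0.189), and its 3 probes lay between -0.15 and 0.02.

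Type I interferon-stimulated genes fell as a list: of 34 measured, 0 were higher and 9 lower over all genes and over the list alone, with a median of -0.22. Usp18, which removes ISG15 from proteins, fell most (-1.12 ± 0.18, adjusted p = 0.00978), followed by the antiviral GTPase Mx2 (-0.98 ± 0.22, adjusted p = 0.0240). The adjusted p was 0.00498 with camera, 0.167 with fry, 0.686 with an estimated correlation and 0.243 among genes above the median signal. With the unrepaired normexp correction the list pointed upwards (adjusted p = 0.760), and with the repaired one downwards (0.00968). The number lower was 5 after cyclic loess normalization, 3, 4 and 1 without TGC3 1 to TGC3 3 and 2, 4 and 1 without TG 1 to TG 3. Other cell markers had the positive medians given above (at the bounds, neutrophil 1.83, B cell 0.69, hepatocyte 0.32, dendritic cell 0.48). Interferon-gamma response genes did not pass (30 measured, 2 higher and 3 lower, 0 and 3 over the list alone, adjusted p = 0.401), with a median of -0.04, a mean of 0.06 and a test that pointed downwards. The invariant chain Cd74 was higher (0.76 ± 0.19, adjusted p = 0.0360) and the GTPase Irgm2 lower (-0.62 ± 0.09, adjusted p = 0.00745). Mx2 did not pass without TGC3 1, TGC3 3, TG 1 or TG 3 (adjusted p = 0.0587 to 0.0639), nor Cd74 without any 1 array other than TG 3 (0.0537 to 0.0858).

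Immediate early and dissociation stress genes, which also report handling of cells, had 14 of 29 higher and 2 lower (14 and 3 over the list alone), with a median of 0.39, above all 10000 matched random lists. The list did not pass with camera at the main settings (adjusted p = 0.0694, and 0.762 with an estimated correlation) but passed under several others. Egr1 was the largest increase (1.27 ± 0.22) and the heat shock gene Hspa1b the largest decrease (-1.47 ± 0.36, adjusted p = 0.0301). It passed among genes above the median signal (adjusted p = 1.4e-04), with the repaired and unrepaired normexp corrections (0.0161 and 2.6e-07) and after quantile and cyclic loess normalization (0.0270 and 0.0276). It also passed with the deposited normalized values (0.0275) and without TGC3 2 or TG 3 (0.0101 and 0.0460). The number higher was 7 without TGC3 1 or TGC3 3 and 8 without TG 1 or TG 2. Hspa1b did not pass without TGC3 1, TGC3 2, TG 1 or TG 3 (0.0637 to 0.0787). The same positive marker medians stand beside this list. Of 28 apoptosis and survival genes, 2 were higher and 5 lower over all genes and over the list alone (median -0.04, adjusted p = 0.198). The cell cycle inhibitor Cdkn1a (0.79 ± 0.23, adjusted p = 0.0484) and the pro-apoptotic Bad (0.60 ± 0.15, adjusted p = 0.0353, 1 of 2 probes) were higher. Cdkn1a did not pass without any 1 array other than TGC3 2 (0.0882 to 0.130), nor Bad without any 1 array other than TGC3 3 (0.0587 to 0.104).

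Among metabolic lists, camera at the preset correlation called cholesterol and fatty acid synthesis genes lower (26 measured, 0 higher and 5 lower over all genes and over the list alone). Over all genes, 21 passed neither way. The median of the list, -0.13, lay within the central 95% of matched random lists (-0.14 to 0.05), and the list was not called among genes above the median signal (adjusted p = 0.212). The elongase gene Elovl6 was among the largest (-0.58 ± 0.11, adjusted p = 0.0152). Ribosomal protein genes were lower by a median of -0.06 (46 measured, 0 higher and 2 lower, 0 over the list alone), a smaller fall than the median of matched random lists (-0.09). The list was not called among genes above the median signal (adjusted p = 0.198), after quantile normalization (0.217) or with the deposited normalized values (0.169), and its median was 0.04 after cyclic loess normalization (0.961). The 2 were Rps15 (-0.25 ± 0.07, adjusted p = 0.0483) and Rpl18 (-0.22 ± 0.06, adjusted p = 0.0423). With camera, fry and an estimated correlation the adjusted p was 0.00667, 0.0175 and 0.554 for cholesterol and 0.00620, 0.144 and 0.741 for ribosomal genes. Both lists pointed upwards with the unrepaired normexp correction (adjusted p = 0.760 and 4.6e-06), and downwards with the repaired one (0.0161 for both). The number of cholesterol genes lower was 3 without TGC3 1, TGC3 3 or TG 1 and 2 without TG 2, and that of ribosomal genes 4 without TGC3 2, 0 without any other array, 5 with the repaired normexp correction and 7 among genes above the median signal. Both lists stand beside the positive medians of neutrophil, B cell, hepatocyte and dendritic cell markers (1.83, 0.69, 0.32 and 0.48 at the bounds). Glycolysis genes did not pass (23 measured, 1 higher and 4 lower, 1 and 2 over the list alone, median 0.04, mean -0.04, test downwards, adjusted p = 0.346). Of these, Slc16a1, a lactate transporter, was lower (-0.52 ± 0.12, adjusted p = 0.0245, 2 of 3 probes) and Aldoc higher (0.51 ± 0.12, adjusted p = 0.0284, 1 of 2 probes). Oxidative phosphorylation genes did not pass (43 measured, 1 higher and 1 lower, 1 and 0 over the list alone, median -0.09, adjusted p = 0.0543). These were Cox7c (0.49 ± 0.08, adjusted p = 0.00850) and Atp5e (-0.32 ± 0.08, adjusted p = 0.0329). The oxidative phosphorylation list passed without TGC3 2 and without TG 2 (adjusted p = 0.00380 and 0.0220). Calls were lost for Elovl6 without TG 1 (0.0521), Rps15 without any 1 array other than TGC3 2 (0.0704 to 0.139) and Rpl18 without any 1 of the 6 arrays (0.0635 to 0.133). They were also lost for Slc16a1 without TGC3 3, TG 1 or TG 2 (0.0557 to 0.0781), Aldoc without any 1 array other than TGC3 2 (0.0611 to 0.0870) and Atp5e without any 1 array other than TGC3 2 (0.0738 to 0.101).

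Genes near Cxcr3 on the X chromosome, listed because they flank the deleted gene, did not pass as a list (34 measured, 4 higher and 6 lower, 4 and 7 over the list alone, median -0.01, mean 0.003, test downwards, adjusted p = 0.549). The 2 largest changes by the rule for named genes were those of Kif4, a mitotic kinesin that is also in the G2 and M phase list (1.41 ± 0.24, adjusted p = 0.0109), and Ercc6l, a helicase of mitotic chromosomes (0.64 ± 0.12, adjusted p = 0.0137, 1 of 2 probes).

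Markers of other liver and blood cells were measured because sorted cells can hold some of them. B cell markers were the only list of this kind called by camera (10 measured, 7 higher and 2 lower over all genes and over the list alone, median 0.69, adjusted p = 0.0450). Its adjusted p was 0.0175 with fry and 0.563 with an estimated correlation, 0.0568 without TG 1 and 0.0571 after quantile normalization. With the unrepaired normexp correction the list pointed downwards (adjusted p = 0.198), and with the repaired one its median was 0.25 without passing (0.173). Ms4a1, which encodes CD20, was at least 3.52-fold higher, the IgM receptor gene Fcmr at least 3.89-fold and Ly6d at least 4.64-fold (2.42, 2.70 and 3.43 without TGC3 2, the lowest without any 1 array). These 3 were above background on no TG array and passed the filter through the TGC3 arrays alone. The list's call and count thus rest in part on members kept because they were high in TGC3. Neutrophil markers had a median of 2.98, which without 1 array ran from 2.19 (without TGC3 2) to 3.70 (without TG 3) and at the bounds was 1.83 (5 measured, 2 higher and 1 lower, 4 and 1 over the list alone, adjusted p = 0.160). The calprotectin genes S100a9 (at least 107.2-fold higher, adjusted p = 0.00254, measured on 1 of 3 TG arrays) and S100a8 (at least 28.2-fold higher, adjusted p = 0.00211) rose, by at least 69.5-fold and 17.6-fold without TGC3 2, and the protease gene Mmp9 fell (-2.31 ± 0.16, adjusted p = 0.00123). S100a8 was above background on no TG array and, like the B cell markers just named, passed the filter through the TGC3 arrays alone. Plasma cell markers had a median of 0.00 (6 measured, 2 higher and 1 lower over all genes and over the list alone, adjusted p = 0.873). The joining chain Jchain was at least 5.55-fold higher (adjusted p = 0.00626, measured on 1 of 3 TG arrays) and Ighm lower (-0.88 ± 0.16, adjusted p = 0.0139). For each bound, a value not well above background was set to the lowest value of any probe well above background on that array, or left as it was if higher. At such bounds the medians of most lists were the same or moved by at most 0.02, apart from those of neutrophil, hepatocyte (0.32) and CD4 and regulatory T cell markers (-0.13).

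With the unrepaired normexp correction the medians of the remaining lists of other liver cells turned below 0, and with the repaired one they stayed above 0 (0.05 to 0.26). The macrophage, cholangiocyte, endothelial and stellate, and erythroid and platelet medians lay within the central 95% of random lists matched on signal. These ranges ended at 0.50, 0.74, 0.45 and 0.56. Macrophage and monocyte markers had a median of 0.35 (11 measured, 4 higher and 0 lower over all genes and over the list alone, adjusted p = 0.0690). They included lysozyme Lyz2 (3.22 ± 0.81, adjusted p = 0.0334) and Mpeg1 (1.35 ± 0.30, adjusted p = 0.0243). Dendritic cell markers had a median of 0.48 (14 measured, 5 higher and 1 lower, 7 and 1 over the list alone, adjusted p = 0.0690). The transcription factor Zbtb46 was higher (1.36 ± 0.11, adjusted p = 0.00168). The macrophage list passed without TGC3 1 and without TG 3 (adjusted p = 0.0315 and 0.0460), and the dendritic cell list without TG 3 (0.0492). Hepatocyte markers had a median of 0.64, or 0.32 at the bounds and 0.32 without TG 1 (6 measured, 3 higher and 0 lower over all genes and over the list alone, adjusted p = 0.0859). Higher were G6pc (0.84 ± 0.15, adjusted p = 0.0114) and transferrin, Trf (0.83 ± 0.07, adjusted p = 0.00171). For cholangiocyte markers the median was 0.46 (5 measured, 2 higher and 0 lower, 3 and 0 over the list alone, adjusted p = 0.146). The largest was osteopontin, Spp1 (at least 1.85-fold higher, adjusted p = 0.00932, measured on 1 of 3 TG arrays). For endothelial and stellate cell markers it was 0.23 (12 measured, 4 higher and 1 lower over all genes and over the list alone, adjusted p = 0.208). Clec4g (0.84 ± 0.08, adjusted p = 0.00244) and Stab2 (0.72 ± 0.07, adjusted p = 0.00274), genes of liver sinusoids, were the largest. For erythroid and platelet markers it was 0.49 (6 measured, 3 higher and 0 lower over all genes and over the list alone, adjusted p = 0.0942). Slc4a1, or band 3 (0.98 ± 0.20, adjusted p = 0.0174), and the globin Hbb-bt (0.54 ± 0.11, adjusted p = 0.0171) were the largest past the threshold. Calls were lost for Lyz2 without TGC3 3, TG 2 or TG 3 (adjusted p = 0.0735 to 0.0963), Mpeg1 and Slc4a1 without any 1 TG array (0.0678 to 0.0706 and 0.0527 to 0.0554) and Hbb-bt without TGC3 3, TG 1 or TG 2 (0.0530 to 0.0593).

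In all, 12 of 35 tested lists passed with camera at the preset correlation, 3 higher and 9 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.554. Beyond the lists for which such counts are given, leaving out 1 array moved the number of members higher or lower by at most 5. In lists with few calls this could be most or all of them. Without TG 1 or TG 2 the number higher went from 3 to 0 for erythroid and platelet and from 4 to 1 for macrophage markers. Without TGC3 1, inhibitory receptors went from 3 higher and 0 lower to 1 and 3. B cell markers kept 5 to 7 higher. Fry, which asks whether a list's own genes move 1 way on balance and does not compare them with other genes, passed 11 lists, among them hepatocyte, cholangiocyte, endothelial and stellate, and erythroid and platelet markers.

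The 12 increases of single genes taken by the fitted change, an order that rests in part on TG values not above background, included S100a9 and S100a8 and held transcripts of immunoglobulins and B cells besides genes with no common function. Igh-VJ558, an immunoglobulin heavy chain variable gene, rose by 4.84 ± 0.72 (adjusted p = 0.00727), but its 7 probes ranged from -0.16 to 4.84 and 3 passed. The light chain gene Iglv1 rose by 3.61 ± 0.74 (adjusted p = 0.0185), with 4 probes from 0.59 to 3.61 of which 3 passed, and did not pass without TGC3 2 or any 1 TG array (adjusted p = 0.0514 to 0.0587). Sh2d1b1, which encodes the adaptor EAT-2, was at least 8.37-fold higher, Adamts2, a procollagen protease gene, at least 9.61-fold, Speer6-ps1 at least 5.67-fold and the chemokine gene Cxcl14 at least 4.69-fold. Likewise the olfactory receptor gene Olfr1378 was at least 4.54-fold and Piwil1, of the Piwi family, at least 2.01-fold higher. Such bounds moved both ways without 1 array. From without TGC3 1 to without TGC3 3 they ran from 3.38 to 7.23 for Olfr1378, 6.17 to 9.84 for Sh2d1b1 and 3.66 to 6.58 for Cxcl14. For Piwil1 the bound was 1.51 without TGC3 2 and 2.35 without TGC3 1. Ms4a1 and Fcmr complete the 12. All 12 were above background on every TGC3 array, and 9 of them on no TG array.

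The 12 decreases taken by the fitted change were led by Cxcr3, and 9 of them were above background on no TGC3 array. Olfr1371, an olfactory receptor gene, was at least 8.78-fold lower, Samt1c at least 4.33-fold, Slfn14 at least 3.66-fold, and the testis gene Brdt at least 2.83-fold. Hspa12a was at least 2.40-fold, Entpd3 at least 2.15-fold, Atp8b3 at least 2.04-fold, Trpm1 at least 1.69-fold and the tetraspanin gene Tspan15 at least 1.59-fold lower. Mmp9 (-2.31 ± 0.16, adjusted p = 0.00123) and Tmem273 (-2.01 ± 0.28, adjusted p = 0.00602) were measured on all 6 arrays. Slfn14 did not pass without TG 1 or TG 2 (adjusted p = 0.0542 to 0.0565). Bounds of these decreases also moved without 1 array, as for Samt1c, from 3.02 (without TG 1) to 6.06 (without TG 3).

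**Figure D3:**
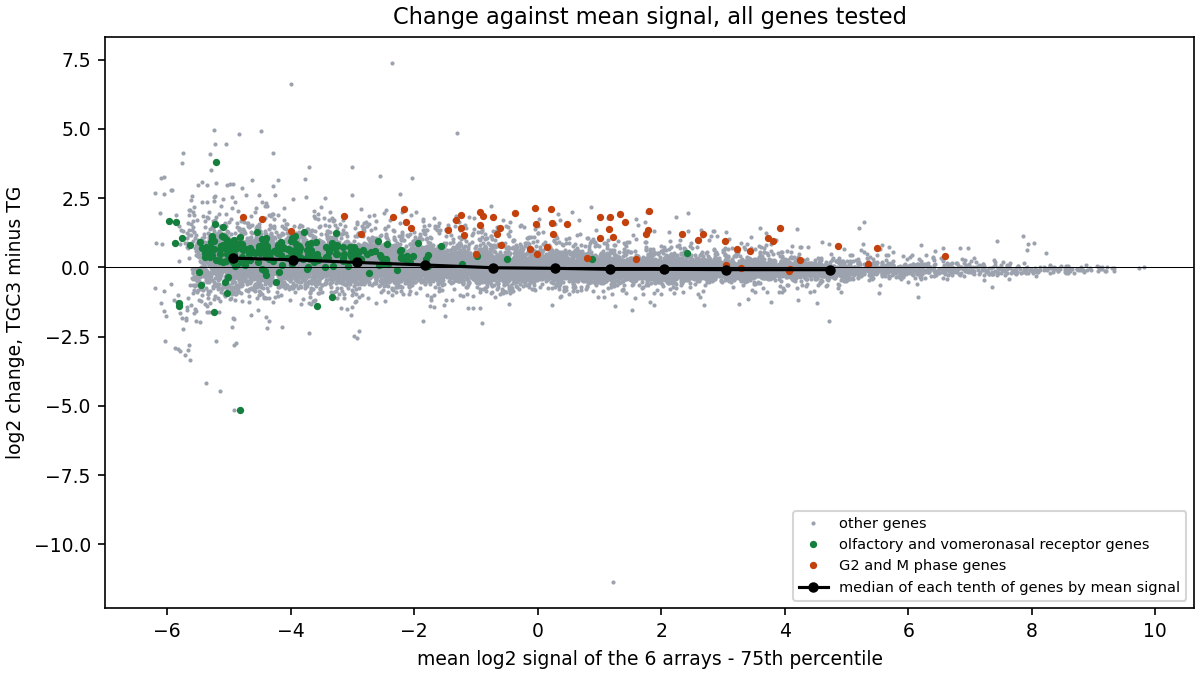
Each point is 1 of 16389 genes, with the mean log2 signal over the 6 arrays (minus the 75th percentile) on the horizontal axis and the log2 change (TGC3 minus TG) on the vertical axis; olfactory and vomeronasal receptor genes are green, G2 and M phase genes orange, and black marks are medians of deciles of the genes. Medians ran from 0.33 in the dimmest decile to -0.08 in the brightest, and the receptor genes had a median of 0.54, which turned to -0.70 with the unrepaired normexp correction and was 0.14 with the repaired one.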

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

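Cyclic loess normalization, genes above the median signal only and normexp with aberrant spot backgrounds replaced were chosen after seeing the data, as were the genes named outside the rule. Over all settings, the changes of 106 named genes besides Cxcr3 kept their side of the threshold in 1700 values, lost the call in 300, gained it in 7 and reversed in 27, and the 30 other lists did so in 572, 35, 34 and 9. All 27 and 9 reversals came with the unrepaired normexp correction. A value past the threshold in neither setting counted as kept even if its sign changed, as it did in 51 values of genes and lists. Cxcr3 was lower under every setting. Signal over background sets which genes could be read: 13298 of 41174 probes were well above background on no array. The slide and the scan run could not be fitted as blocks, since 0 slides and 0 runs held both groups, nor the scan date, since all 6 arrays shared 1 day.

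With the replicate number as a block, 1790 genes were higher and 553 lower. The numbers do not pair the samples: deviations from the group means correlated at -0.003, -0.077 and -0.099 between arrays of the same number and at -0.015 to 0.103 between others.

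Without 1 array, the count of genes higher ran from 1756 (without TG replicate 2) to 2359 (without TGC3 replicate 2), of genes lower from 572 (without TG replicate 1) to 1508 (without TGC3 replicate 2), and of genes at least 2-fold lower from 82 (without any 1 TG array) to 136 (without TGC3 replicate 2). The other lower counts were 738 and 756 without TGC3 replicates 1 and 3, and 610 and 814 without TG replicates 2 and 3. The adjusted p of cytotoxic effector molecules ran from 0.00238 (without TGC3 replicate 2) to 0.0668 (without TGC3 replicate 3), with 0.0607 without TG replicate 3. An array fewer is the construction of these settings; what set the single arrays apart was not tested.

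Array weights gave 2420 genes lower and 138 at least 2-fold lower, no filter 579 lower (27338 genes tested, median change 0.13), and a filter on all 6 arrays 46 at least 2-fold lower. Genes above the median signal, fewer by construction, gave 736 higher, 79 at least 2-fold higher, 16 at least 2-fold lower and 4 lists called. Cytotoxic effector molecules and naive and central memory genes were not called after quantile normalization (adjusted p = 0.0571 and 0.0933), with the deposited normalized values (0.0571 and 0.0946), after cyclic loess (0.0708 for both) or among genes above the median signal (0.176 and 0.214). Fry gave 0.0962 for cytotoxic effector molecules and 0.0646 for S phase genes. With an estimated correlation, 0 lists were called, with 0.554 for G2 and M phase and for naive and central memory genes and 0.686 for S phase and for cytotoxic genes. Except where the construction shows it, the cause was not tested.

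Normexp background correction gave 0 genes higher and 1 lower, with 0 and 1 at least 2-fold (507 at an unadjusted p under 0.05 in limma). TG replicate 3 held 7 spots with a local background over 10 times its median, the highest 65262 against a median of 44, and the other arrays held 0. With these replaced, 2039 genes were higher, 1873 lower, 153 at least 2-fold higher and 28 at least 2-fold lower. Unrepaired, it reversed the direction of the camera test for cytotoxic effector molecules (adjusted p = 0.546), naive and central memory (0.760, median still -0.04), B cell (0.198), T cell receptor signalling (0.0220), cholesterol and fatty acid synthesis (0.760), cytokine receptor and JAK-STAT (0.124), glycolysis (0.0127), interferon-gamma response (0.00371), oxidative phosphorylation (4.8e-07), ribosomal protein (4.6e-06) and type I interferon-stimulated genes (0.760). Single genes reversed as well, none past the threshold: Atp5e (0.11), Cd5 (0.029), Ctsw (0.057), Rpl18 (0.24) and Rps15 (0.20) upwards, and Acvr1 (-0.70), Bad (-0.38), Cd200 (-0.15), Cdkn1a (-0.13), Clec4g (-0.46), Cxcl14 (-0.014), Ercc6l (-0.12), Fcmr (-0.22), G6pc (-0.59), Hbb-bt (-0.48), Il1rl1 (-0.39), Jchain (-0.021), Ltbp1 (-0.64), Ly6d (-0.11), Mpeg1 (-0.27), Ms4a1 (-0.16), Olfr1378 (-0.11), Piwil1 (-0.42), Slc4a1 (-0.48), Spp1 (-0.71), Stab2 (-0.20) and Trf (-0.46) downwards.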

Other observations

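The splits of the cell cycle, activation, cytotoxic and naive lists and of the list count, the median of the receptor genes and the share after quantile normalization were fixed beforehand, and the tests on control probes, slides and matched lists, the downward markers, the splits of the 4 gene counts, and the kinesin and centromere families were chosen after the result was seen.

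Kinesins outside the cell cycle lists held mitotic members that rose in TGC3. Of 22 measured, 7 were higher and 1 lower, with a median change of 0.15 that turned to -0.04 among genes above the median signal. Kif14 (1.98 ± 0.19, adjusted p = 0.00231) and Kif18b (1.90 ± 0.20, adjusted p = 0.00317), motors of dividing cells, changed most, and the neuronal kinesin Kif5a fell (-0.71 ± 0.12, adjusted p = 0.01003). Of 18 centromere protein genes outside the lists, 9 were higher and 1 lower, with a median of 0.49, and of 0.10 among genes above the median signal. Cenpi rose by 1.40 ± 0.22 (adjusted p = 0.00867), and Cenpj, a centriole protein despite its symbol, fell (-0.36 ± 0.08, adjusted p = 0.0223), not past the threshold without TGC3 replicate 3 or any 1 TG array (0.0539 to 0.0628).

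More genes were at least 2-fold higher than lower in TGC3 (512 against 90), and most of both were dim: the dimmest 3 deciles held 149, 92 and 75 of those higher and 40, 13 and 9 of those lower. Different signal distributions left by the scaling are argued against as the whole cause, since after quantile normalization 75.1% of such genes were higher. A greater abundance of these transcripts in TGC3 cells is argued against for the family tested alone and stays open for other dim genes, since olfactory and vomeronasal receptor genes, which T cells are not known to use, had a median change of 0.54 (0.49 to 0.59 by bootstrap) against 0.24 for genes matched by signal decile, with 125 of 229 higher and 3 lower (Olfr1371, Olfr48 with -1.39 ± 0.10 and Vmn1r79 with -0.54 ± 0.13, the latter not past the threshold without TGC3 replicate 1 or 3 or TG replicate 1 or 3, adjusted p = 0.0665 to 0.0846), a median of 0.14 with the repaired normexp correction and -0.70 with the unrepaired one. Weakly matched RNA bound more on the slide of the TGC3 arrays may account for part of the excess: within each of 3 sets of spike-in control probes, those with names ending in 7, taken as weaker matches from their lower level, read higher against those ending in 0 on TGC3 arrays, by 0.425 in the mean (0.15, 0.52 and 0.61), with no overlap between slides. Weak matching stays a hypothesis, since the names of the control probes are not explained in the files. The argument from the receptor genes holds only under the premise that T cells do not use them. Receptor genes above background on the 3 arrays of 1 group alone could pass the filter, so that a rise itself helped to keep some.

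For the G2 and M phase genes higher in TGC3, weakly matched RNA bound more on the slide of the TGC3 arrays is argued against as the whole cause only so far as it follows signal. The list's median of 1.27 (1.11 to 1.48 by bootstrap over genes) lay at percentile 100 of 10000 lists matched on signal, the highest of which reached 0.09. Bootstrap and random lists treat genes as independent, while the list's estimated correlation was 0.78, so that neither measures the spread between samples. Weak matching that differs between probes of like signal was not tested. Dividing cells of another type among the sorted cells stay open: 4 lists of markers of other cell types (hepatocyte, B cell, neutrophil and dendritic cell) had medians above the central 95% of their matched lists, although the sort for CD8 would remove most such cells. Only 6 of 28, 10 of 18, 5 of 17 and 14 of 20 of these markers were measured. The hepatocyte median was 0.32 at the bounds and 0.32 without TG replicate 1. Both values lie inside the central 95% of its matched lists (-0.19 to 0.58). Among genes above the median signal the B cell and dendritic cell medians were -0.54 (2 genes) and -0.10 (6 genes). TGC3 replicate 2 read highest of the TGC3 arrays both for Cenpf (1.48 against 0.80 and 0.79) and for Lyz2 (1.16 against -1.62 and -0.82), and without it the list's median was 1.098. Marker lists did not all follow Lyz2. Without TGC3 replicate 2 the macrophage and B cell medians were 0.34 and 0.695, against 0.35 and 0.69. The cholangiocyte median rose from 0.46 to 0.61, and the neutrophil, hepatocyte and dendritic cell medians fell to 2.19, 0.57 and 0.36. A difference between the 2 slides other than in dim probes cannot be told apart from genotype, since 0 slides held both groups. The loss of CXCR3, the biological difference that the design names, stays among the open explanations.

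Neutrophil and B cell transcripts were among the largest rises in TGC3, with S100a9 at least 107.2-fold higher (measured on 1 of 3 TG arrays), or 69.5-fold without TGC3 replicate 2. Weakly matched RNA bound more on the slide of the TGC3 arrays is not excluded: for the 15 tested neutrophil and B cell markers together the median change was 0.70, at percentile 100 of matched random lists (highest 0.65), but its interval by bootstrap over genes (-0.03 to 3.51) reached below them, as did that of the 5 neutrophil markers alone (median 2.98, or 1.83 at the bounds, -2.31 to 7.39, highest matched list 1.40), and the 10 B cell markers (0.69) lay under their highest matched list (0.95). Ms4a1, Fcmr, Ly6d and S100a8 were above background on no TG array and passed the filter through the TGC3 arrays alone. The random lists were matched on mean signal but not on this, so these percentiles rest in part on members kept because they were high in TGC3. B cells, plasma cells and neutrophils among the sorted cells are not excluded either: of 21 markers tested 11 were higher, but 4 passed the threshold downwards (Mmp9, Ighm, Cd72 with -1.05 ± 0.12, and Cd22 with -0.92 ± 0.22, the latter not past the threshold without any 1 array other than TGC3 replicate 2, adjusted p = 0.0567 to 0.0858). The medians of the neutrophil, B cell and plasma cell lists turned below 0 with the unrepaired normexp correction, to -0.10, -0.35 and -0.24, and were 0.77, 0.25 and 0.00 with the repaired one. The genotype stays open here as well.

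The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2721 genes higher, 1552 lower, 512 at least 2-fold higher and 90 at least 2-fold lower, and the highest of the other splits gave 1 for each count, so that 1 split reached each real count. For the number of lists called, the real value was 12 and the highest other 13, and 2 splits reached the real value. For single lists the real camera p and the smallest p of the other splits were 1.8e-09 and 3.0e-19 for S phase genes (3 splits as small), 2.9e-21 and 1.9e-16 for G2 and M phase genes (1 split), 0.757 and 0.0507 for T cell activation markers (7 splits), 0.00822 and 3.6e-06 for cytotoxic effector molecules (3 splits), and 0.00497 and 2.8e-04 for naive and central memory T cell genes (2 splits).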
